A study of Fagopyrum esculentum with 5 samples.

How the data were processed

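The series holds 5 libraries of RNA from developing seed of common buckwheat (Fagopyrum esculentum), 1 library for each of 5 successive developmental stages. No stage has a second library, and the labels do not say how many seeds or plants went into each one, or how many days separate the stages. The stage number was therefore used as an order and not as a time.

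Each deposited table lists tags of 21 bases, every one of them CATG followed by 17 further bases, with the copy number of the tag in that library. Tags of this form come from digital gene expression profiling, in which cDNA is cut at CATG and the stretch beside the cut is counted. Per the labels' protocols, however, poly(A) RNA was fragmented and copied with random hexamers before sequencing on an Illumina HiSeq, and that text speaks of pear fruit as the starting material. All listed sequences begin with CATG, so the tables were treated as tag counts. The tag caller, filters and software are not given in the sources used here.

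The copy numbers deposited by the authors are whole-number counts. No table lists a tag with fewer than 2 copies, so an unlisted tag had at most 1 copy in that library. The second deposited column is headed TPM per the file headers. It equals the copy number divided by the sum of the listed copy numbers, times 1000000, to within 0.005, so it holds no information beyond the counts. The TPM values reported here were recomputed from the counts in that way, so TPM stands for copies of a tag per 1000000 listed copies. Total copies per library ran from 5712280 to 5998809, and 1 copy was worth 0.167 to 0.175 TPM. A tag at 10 TPM rested on 57.1 to 59.99 copies. Intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

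No reference genome or transcript set of buckwheat was used here, so tags are reported by sequence, without gene names or positions. The gene lists fixed before the data were examined (storage proteins, oil bodies, starch and flavonoid synthesis and others) could not be matched and were not tested. Positions within a tag are counted from 1 at the C of CATG.

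Because each stage has 1 library, no test between 2 stages was possible. Neighbouring stages, and stage 5 against stage 1, were compared by a rule of size. A tag was called when its TPM were at least 4-fold apart, the exact conditional binomial interval of the ratio excluded 2-fold, and the higher library had at least 10 TPM. An unlisted tag was set to 3 copies in the fold and to 1 copy in the interval. The rule compares the libraries, not the stages. The only test across libraries was edgeR's quasi-likelihood test of a linear slope on stage number over all 5 libraries, with TMM scaling, Benjamini-Hochberg adjustment at 0.05 and 3 residual degrees of freedom. Its spread is the departure of the libraries from a straight line and not replicate error. It ran on 19072 tags with at least 10 TPM in 1 library or more. Correlations are across these tags on log2(TPM + 1), and tags are not independent replicates.

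Both procedures were tested on simulated data. With 19072 simulated tags for the trend over stages and a dispersion of 0.05, the test called 100 of 100 tags with a slope of 1 log2 unit per stage, 68 of 100 with a slope of 0.5, and 5 unchanged tags. That dispersion was assumed, and each unchanged tag had the same mean share in all 5 libraries. These rates therefore do not give the power or the rate of false calls of the trend test in these data. For stage 2 against stage 1, with Poisson counts for 19072 tags, the rule of size called 100 of 100 tags changed 8-fold and 0 unchanged tags. Apart from the changed tags, both simulated libraries had the same mean profile. The simulation of the rule thus held no shift in composition and no noise beyond counting, and does not give its rate of false calls in these data.

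Tags named in the text were chosen by a rule. They are the 3 most abundant tags of each library, the 2 called tags with the largest ratio in each direction of each comparison among tags with at least 3 copies in both libraries, the 2 tags in each direction with the smallest adjusted p of the trend test among tags reaching 100 TPM, and the 2 most abundant tags listed in 1 library alone. The rule, the tests and most alternatives were set before the data were examined. The alternatives were TMM and median-of-ratios scaling, other folds and abundance minimums, an exact binomial test, merging of tags 1 base away from a tag at least 100 times as abundant in the same library, other pseudocounts, DESeq2 for the trend, and leaving out each library. The settings with unlisted tags at 1 copy, with up to 2 copies allowed elsewhere, and the peak counts without stage 1 were chosen after seeing the data. Analyses used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, SciPy 1.17.1 and NumPy 2.4.6.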

Results

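Common buckwheat is a pseudocereal of the knotweed family, grown for a starchy seed that also stores globulin proteins and flavonoids. Messenger RNA of its developing seed was profiled as short sequence tags at 5 successive stages, numbered 1 to 5, to follow how the transcript population changes during seed development. The libraries were of nearly equal depth. Stage 1 gave 5998809 tag copies, stage 2 gave 5875584, stage 3 gave 5846078, stage 4 gave 5712280 and stage 5 gave 5913358. Across the libraries 242991 different tags were listed, of which 41079 were in all 5 and 116095 in 1 alone. There are no replicates, so each value below describes 1 library, and a difference between 2 stages has no replicate check.

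The number of different tags was highest at stage 1 and lowest at stage 3. Stage 1 held 153085 different tags, stage 2 held 101588, stage 3 held 95583, stage 4 held 97162 and stage 5 held 116529. Thinned to the same 5712280 copies, the libraries held 148857, 99927, 94319, 97162 and 114127 tags in stage order, so the small differences in depth did not set the ranking. Equal totals did not equalise the copies left for rarer tags. Outside the 235 tags among any library's top 100 lay 82.9, 46.0, 41.9, 42.2 and 55.8% of copies in stage order. The tag counts rank in the same way, so more different tags need not mean more different transcripts. The 10 most abundant tags took 3.57% of all copies at stage 1 (interval 3.56 to 3.59), 20.01% at stage 2 (19.98 to 20.04), 24.6% at stage 3 (24.599 to 24.669), 24.9% at stage 4 (24.88 to 24.95) and 18.4% at stage 5 (18.33 to 18.397). The 100 most abundant took 14.9% at stage 1, 47.5% at stage 2, 52.6% at stages 3 and 4, and 41.6% at stage 5. Stage 1 had 61 tags at 1000 TPM (copies of a tag per 1000000 listed copies of its library) or more, holding 11.6% of its copies, while stage 3 had 122 such tags, holding 55.1%.

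**Figure D1:**
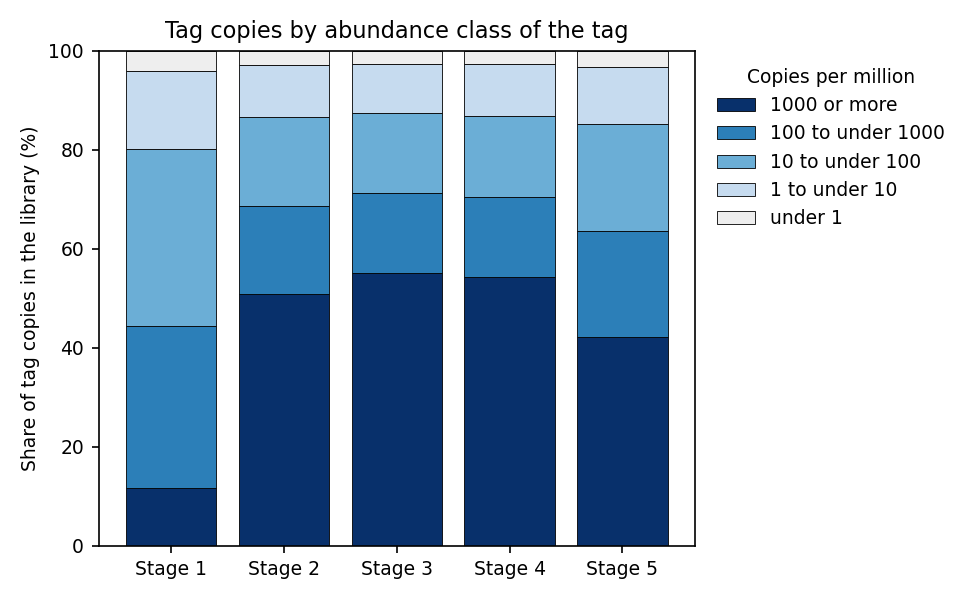
Share of tag copies (vertical axis, percent of the library) held by tags of 5 abundance classes in TPM, for 1 library per stage. Tags at 1000 or more held 11.6% of stage 1 copies, 50.9% of stage 2, 55.1% of stage 3, 54.2% of stage 4 and 42.2% of stage 5.

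The most abundant tags fell into distinct courses. CATGTTATTAAAGTTTACTAA was at 132 TPM at stage 1 (interval 123 to 142) and at 27730 at stage 2, and it was the most abundant tag of stages 3 and 4, at 79884 (79664 to 80104) and 63232, before 32463 at stage 5. CATGCTGCTTTAATATATGTT was at 138 TPM at stage 1, 36157 at stage 2, 18296 at stage 3, 40742 at stage 4 and 34368 at stage 5, where it was the most abundant tag. CATGCTGTTTTAATATATGTT, which differs from it by C8T, was at 30.5 at stage 1 and at 27404, 25950, 27313 and 18171 at stages 2 to 5. CATGCATGCAACCTAAATACT was at 26.0 TPM at stage 1 (22.1 to 30.4), 12297 at stage 2, 12841 at stage 3, 17132 at stage 4 and 19441 at stage 5.

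A second course had its low point at stage 5. CATGTGGTTTTGATGGGTAAA, the most abundant tag of stage 1 at 4712 TPM, was at 30092 at stage 2, 32499 at stage 3, 19359 at stage 4 and 1128 at stage 5 (1101 to 1156). CATGGGGATCGGAACTAGGGA was at 4286 TPM at stage 1, 12042 at stage 2, 12475 at stage 3, 16328 at stage 4 and 626 at stage 5 (606 to 647). CATGGGATAACATTATAGGAT differed from both, with 3846 TPM at stage 1, 2231 at stage 2, 1115 at stage 3, 182 at stage 4 (171 to 193) and 1774 at stage 5.

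**Figure D2:**
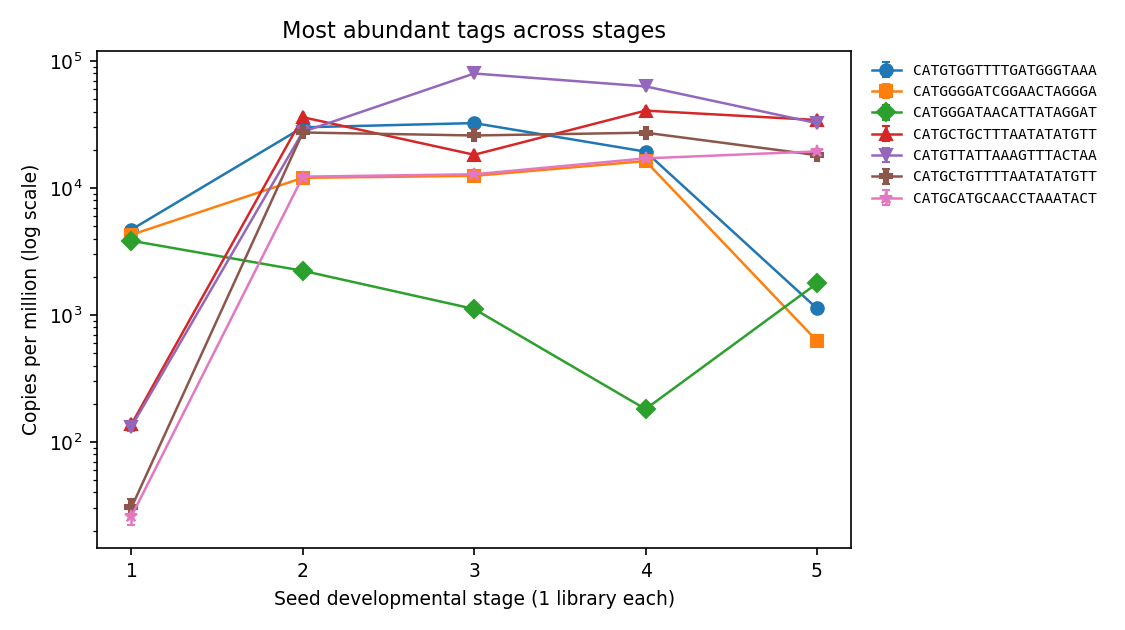
Copies TPM (log scale) of the tags among the 3 most abundant of any library, against seed developmental stage, with exact 95% counting intervals that are mostly smaller than the symbols. The 4 tags at 138 TPM or less at stage 1 were at 12297 or more at stages 2 to 5, while CATGTGGTTTTGATGGGTAAA and CATGGGGATCGGAACTAGGGA were lowest at stage 5, at 1128 and 626.

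Stages 2, 3 and 4 resembled each other, and stages 1 and 5 stood apart. Across 19072 tags, Pearson's r was 0.93 between stages 3 and 4 (Spearman's rho 0.90), 0.88 between stages 2 and 3 (rho 0.84) and 0.86 between stages 2 and 4 (rho 0.81). It was 0.73 between stages 4 and 5 (rho 0.67) and 0.62 between stages 2 and 5. Stage 1 correlated at 0.37 with stage 2 (rho 0.34), 0.25 with stage 3, 0.26 with stage 4 and 0.06 with stage 5 (rho 0.04). These values depended on the abundance minimum. Over all 242991 tags r was 0.75 between stages 1 and 2 and 0.60 between stages 1 and 5, and among tags reaching 100 TPM in any library it was 0.0766 and -0.28.

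**Figure D3:**
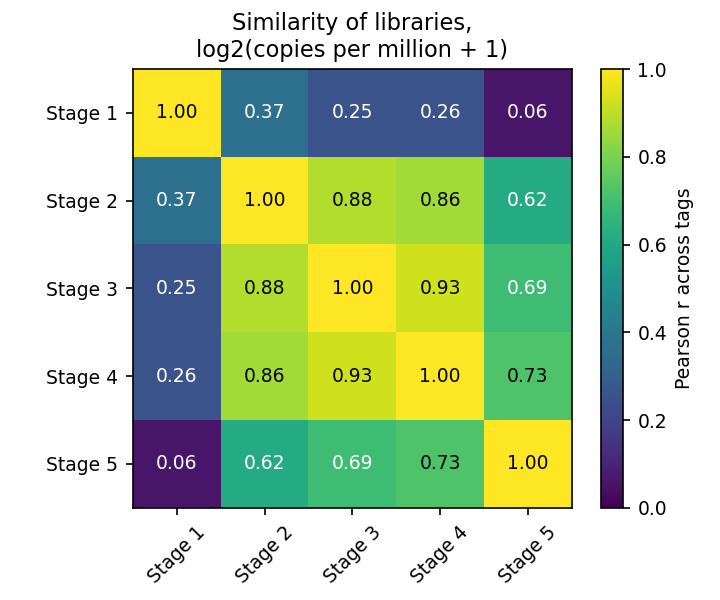
Pearson's r between each pair of libraries across 19072 tags, on log2(TPM + 1), with colour from 0 to 1. The block of stages 2, 3 and 4 lies between 0.86 and 0.93, and the stage 1 row lies at or below 0.37 outside the diagonal.

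Stage 2 differed from stage 1 in the tags that held most of the stage 2 copies. Under the rule of size 1645 tags were higher in stage 2 and 6234 were lower. The higher tags took 4.31% of copies at stage 1 and 56.6% at stage 2, and 98 of them reached 1000 TPM. The lower tags took 35.9% of copies at stage 1 and 4.66% at stage 2. The largest ratios belonged to CATGAGAGGTATAGGAGGAAG, 1133-fold higher (interval 520.1 to 3087; 6 and 6656 copies), and CATGTATGCTGCCTTAATATA, 1127-fold higher (629.5 to 2258; 11 and 12140 copies). In the other direction CATGTACGTTATACTAAATTA was 563-fold lower in stage 2 (192 to 2732; 1724 and 3 copies) and CATGGGCTTGTACTCATATTT was 313-fold lower (158 to 725; 2553 and 8 copies). With TMM scaling the ratios of these 4 tags became 2613-fold and 2599-fold higher, and 244-fold and 136-fold lower. The balance of higher and lower tags rested on the scaling. TMM scaling moved stage 2 against stage 1 by 1.21 on the log2 scale, and the split became 2709 higher and 1288 lower, or 67.8% higher in place of 20.9%. All 1645 higher tags and 1288 of the 6234 lower tags were called under both scalings.

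**Figure D4:**
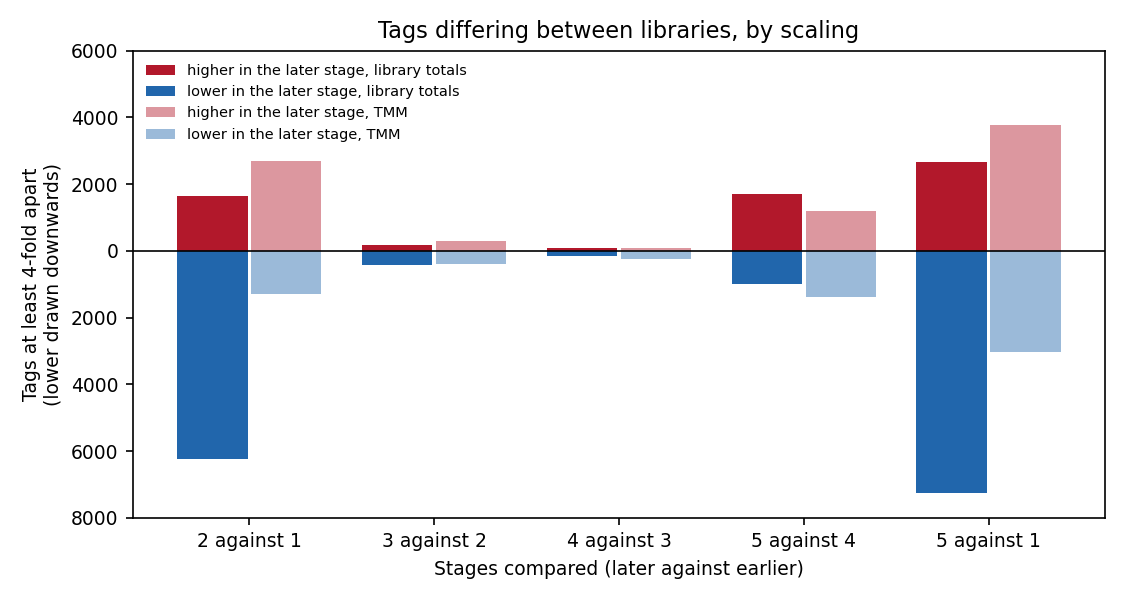
Number of tags at least 4-fold apart between 2 libraries, drawn upwards when higher and downwards when lower in the later stage, with libraries scaled to their totals (dark) or by TMM (pale). Stage 4 against 3 gave 88 higher and 166 lower tags on library totals, and stage 5 against 1 gave 2651 and 7252.

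From stage 2 to stage 3 few tags differed. There were 172 higher and 415 lower tags, 6.67% of the 8800 tags at 10 TPM or more, and TMM gave 289 higher and 400 lower. The higher tags took 0.163% of copies at stage 2 and 1.08% at stage 3, and the lower ones 2.31% and 0.342%. CATGGGAATTCATCCATCAAA was 94.1-fold higher in stage 3 (31.9 to 459; 3 and 281 copies) and CATGCAAATTTGAGGAAAAAA was 48.2-fold higher (31.7 to 77.2). The second had 22 copies at stage 2, where a tag differing from it by 1 base (C6A) had 15097. That is beyond the 100-fold ratio used for merging error neighbours, and the interval does not cover such errors. CATGTCGTTTTTAGGCAACAA was 145-fold lower (73.4 to 337; 1167 and 8 copies) and CATGATGTTATAAATAAAAAA was 122-fold lower (51.9 to 376). At stage 4 or stage 5, though not always at both, each of these 4 tags was nearer its stage 2 level than at stage 3. Their choice by extreme ratios at stage 3 favours such a return. CATGGGAATTCATCCATCAAA first moved further away, from 48.1 TPM at stage 3 to 129 at stage 4, and was at 0.338 at stage 5. CATGCAAATTTGAGGAAAAAA was at 180 TPM at stage 3, 8.40 at stage 4 and 114 at stage 5, and CATGTCGTTTTTAGGCAACAA at 83.0 at stage 4 and 21.3 at stage 5. CATGATGTTATAAATAAAAAA was at 104 TPM at stage 2, 0.855 at stage 3, 173 at stage 4 and 155 at stage 5.

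Stages 3 and 4 differed least of all neighbouring stages, with 88 tags higher and 166 lower, 3.16% of the 8031 tags at 10 TPM or more. Under TMM the split was 101 and 240. CATGTTTTATGTTTTTACTTT was 1247-fold higher in stage 4 (632 to 2888; 8 and 9745 copies), yet had 855 copies at stage 2 and was unlisted at stage 5. CATGCATGCTGCCTTAATGTA was 211-fold higher in stage 4 (90.3 to 653; 5 and 1033 copies) and differs by A19G from CATGCATGCTGCCTTAATATA, which was at 2273 TPM at stage 3 and 1854 at stage 4. CATGCATGCAACCTAATACTC was 92.4-fold lower in stage 4 (44.6 to 231; 662 and 7 copies). CATGGGCATCGGAACTAGGGA was 55.6-fold lower (35.8 to 91.4; 1138 and 20 copies) and differs by G7C from the abundant CATGGGGATCGGAACTAGGGA.

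The step from stage 4 to stage 5 was the second large change. In stage 5 1698 tags were higher and 985 lower, 25.1% of the 10694 tags at 10 TPM or more. The higher tags took 1.89% of copies at stage 4 and 12.4% at stage 5. The lower tags took 20.2% at stage 4 and 1.90% at stage 5, and 36 of them had been at 1000 TPM or more. CATGCATGCAACCTAATACTC was 263-fold higher in stage 5 (127 to 654; 7 and 1904 copies). CATGGGAGGTATAGGAGGAAG was 109-fold higher (85.2 to 142; 63 and 7122 copies) and differs by A5G from CATGAGAGGTATAGGAGGAAG, which went from 1846 to 7975 TPM. CATGCCAATTCGAGGAAAAAA was 1232-fold lower in stage 5 (566 to 3358; 7141 and 6 copies) and CATGCCAATTCAAGGAGTTGT was 774-fold lower (302 to 2844; 2992 and 4 copies). With TMM the majority turned to lower tags, 1381 against 1198 higher.

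Over the whole course, stage 5 against stage 1, 2651 tags were higher and 7252 lower, 55.3% of the 17898 tags at 10 TPM or more. The higher tags took 2.14% of copies at stage 1 and 56.8% at stage 5, and the lower tags 46.8% and 3.38%. CATGAGAGGTATAGGAGGAAG, with 6 copies at stage 1 and 47158 at stage 5, was 7973-fold higher (3663 to 21728). CATGCAAGTGTTTATGTTTTA, with 8 and 30203 copies, was 3830-fold higher (1943 to 8872). CATGAGTTACGAGTTTATGAT, at 2247 TPM at stage 1, was 3322-fold lower (1297 to 12193). CATGGAGGAAGCTTGTGCCAC, at 1476 TPM at stage 1, was 2910-fold lower (995 to 14112). With TMM the ratios of these 4 tags became 15466-fold and 7429-fold higher, and 1713-fold and 1500.04-fold lower. TMM scaling gave 3776 higher and 3017 lower, so that 55.6% were higher in place of 26.8%.

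Tags enriched in 1 single stage lay mostly at both ends of the course. Of 19072 tags, 8357 were at least 4-fold above the mean of the other 4 libraries in their highest library. Of these 6541 peaked at stage 1, 267 at stage 2, 89 at stage 3, 68 at stage 4 and 1392 at stage 5. With TMM scaling 1636 peaked at stage 1 and 1273 at stage 5, still above the 380, 195 and 108 of stages 2, 3 and 4. A tag equally high at stages 2, 3 and 4 and absent elsewhere cannot meet this rule. Low counts at these similar stages are thus partly built in. The tags considered also favoured stage 1, with 14547 at 10 TPM or more there and 7616, 6923, 7003 and 8960 at stages 2 to 5. Tags listed in 1 library alone at 10 TPM or more were few. There were 189 in stage 1, 4 in stage 2, 1 in stage 3, 6 in stage 4 and 9 in stage 5.

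The most abundant of these were CATGGTTTGTGTTGTAGTAGC at 170.2 TPM and CATGTCTTCTACTTTACGCAC at 146 in stage 1. The first differs by C10T from CATGGTTTGCGTTGTAGTAGC, which was at 3156 TPM in stage 1. The second differs by T21C from a tag listed at 106 TPM in stage 1 and in no other library. Stage 2 alone held CATGGCTGGAAAACGTTTGCC at 72.0, which differs by C8G from a tag at 247 TPM in that library. It also held CATGACCATTGGGAATTGAAT at 20.8, which differs by A6C from a tag at 3199 TPM there. That tag had 18798 copies against 122, above the 100-fold ratio at which tags were merged as an alternative. Stage 3 alone held CATGTTTTAAAATGGAGGAAA at 14.9. Stage 4 alone held CATGTCCTCGAATAAGGCTAT at 151 and CATGCTTGGAATTTGTAAGGT at 68.6, and stage 5 alone held CATGAGGAGATTGATTTAGTG at 15.2 and CATGCACGTATGAATGAATGG at 12.2. Each could have had 1 copy in the other libraries, at most 0.175 TPM.

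A steady course over all 5 stages was rarely separable from the departures between libraries. By edgeR's quasi-likelihood test of a slope on stage number, 9 tags rose and 127 fell at an adjusted p under 0.05, among 19072. At an unadjusted p under 0.05 the numbers were 1624 and 3214. Among tags reaching 100 TPM the smallest adjusted p of falling tags was 0.0332 (edgeR), for CATGAAGTTAGAAAGAACTGC and CATGCTGTGTGTATTCACATA. With a minimum of 50 TPM the smallest adjusted p (edgeR) was 0.0563, so neither passed, and 0 tags rose and 0 fell (385 and 871 at an unadjusted p under 0.05). The first tag had 1300 copies at stage 1, 10 at stage 2 and none listed later, and the second had 899, 6 and none listed later. No rising tag of that abundance passed the threshold. CATGAAAATAAAGACGTACAC had 1.17, 5.45, 15.1, 55.1 and 139.9 TPM over the stages (slope 1.85 log2 units per stage, edgeR adjusted p = 0.0581). CATGTAAATGGTTTTAATGGA had 2.67, 7.15, 16.1, 35.5 and 108 (slope 1.46, edgeR adjusted p = 0.0584). By edgeR no tag passed when any 1 of the 5 libraries was left out, although 625 to 1679 tags had a positive slope and 1009 to 3248 a negative one at an unadjusted p under 0.05. None passed with unlisted tags set to 1 copy (1997 and 3296 at an unadjusted p under 0.05), and DESeq2 on all 5 libraries called 1289 and 1652.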

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

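Every alternative below except 3 was set before the data were examined; unlisted tags at 1 copy, at most 2 copies elsewhere and the peaks without stage 1 were chosen after seeing the data. The cause of a change was not tested except where fewer tags or libraries entered by construction. Of the called tags, those higher and lower respectively numbered as follows, in the order stage 2 against 1, 3 against 2, 4 against 3, 5 against 4 and 5 against 1. TMM scaling gave 2709 and 1288, 289 and 400, 101 and 240, 1198 and 1381, and 3776 and 3017. Median-of-ratios scaling gave 2723 and 1170, 318 and 378, 104 and 244, 1309 and 1368, and 4115 and 2751. A 2-fold threshold gave 2279 and 10853, 846 and 1670, 549 and 538, 4328 and 1734, and 3838 and 10042. An 8-fold threshold gave 1156 and 2696, 59 and 168, 46 and 60, 508 and 638, and 1904 and 5080. A minimum of 50 TPM gave 633 and 1488, 37 and 100, 26 and 50, 378 and 292, and 885 and 1757. No abundance minimum gave 3673 and 14562, 614 and 1269, 424 and 497, 4282 and 2930, and 6666 and 17779. An exact binomial test of the 2 libraries with at least 2-fold gave 2270 and 10837, 817 and 1630, 510 and 509, 4297 and 1722, and 3831 and 10018. Merging error neighbours kept these counts within 1.5 times. The majority direction changed with either scaling for stage 2 against 1, 5 against 4 and 5 against 1, for stage 4 against 3 with 2-fold and with the binomial test, and for stage 5 against 4 with 8-fold. Of the values of single named tags, 80 were counted as the same. For ratios this meant staying within the main counting interval, and for trend slopes keeping the direction and side of the threshold. Another 4 ratios moved beyond their interval, while 12 slopes lost a call and 5 gained one. Some named ratios of stage 3 against 2, 4 against 3 and 5 against 4 had no value with error neighbours merged. In their lower library a tag 1 base away was at least 100 times as abundant. They were left out of these numbers for merging, so the 80 do not show that every named ratio withstood it.

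Pearson's r in the same order was 0.2928, 0.8517, 0.9011, 0.7004 and -0.0031 with a pseudocount of 0.1. It was 0.478, 0.9156, 0.9469, 0.7678 and 0.2008 with a pseudocount of 10. It was 0.0766, 0.8876, 0.9203, 0.6707 and -0.282 for tags reaching 100 TPM and 0.7476, 0.9014, 0.9223, 0.8222 and 0.5978 with no minimum. With error neighbours merged, the 10 most abundant tags took 3.62, 20.3, 25.0, 25.3 and 18.6% of copies at stages 1 to 5, and the 100 most abundant took 15.1, 48.2, 53.3, 53.3 and 42.1%.

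Peak counts at stages 1, 3 and 4 were 1636, 195 and 108 with TMM, and with a minimum of 50 TPM they were 1612, 90, 29, 21 and 380 at stages 1 to 5. Without stage 1, 444 tags peaked at stage 2. Tags in 1 library alone numbered 17, 1, 0, 2 and 0 at stages 1 to 5 with a minimum of 50, and with up to 2 copies allowed elsewhere 297 at stage 1, 2 at stage 3 and 14 at stage 5. The counts of rising and falling tags were 208 and 1960 with library totals only, 1289 and 1652 with DESeq2's Wald test, 47 and 479 with a total of 10 counts, 0 and 0 with a minimum of 50 TPM (385 and 871 at an unadjusted p under 0.05, edgeR), and 0 and 0 with unlisted tags at 1 copy. They were 0 to 0 without any 1 library, where the smallest adjusted p (edgeR) ran from 0.0805 to 0.303. The setting that kept tags with at least 2 copies, and the one allowing 1 copy elsewhere, moved nothing because no table lists a tag at 1 copy. The gene lists and their alternative were not run. Depth limits unlisted tags to at most 1 copy, or 0.175 TPM.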

Other observations

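The tests of another organism, of library orders at an unadjusted p, of sequencing errors under tags reaching 2000 TPM and of sequence variants in the plants sampled, the sets of linked tags and the shares of tags ending in A were chosen after the results were seen.

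Many abundant tags belonged to sets of linked sequences. Of 2316 tags reaching 100 TPM in any library, 499 fell into 175 sets whose members were linked by 1 base difference or by an overlap of neighbouring CATG sites. A set of 27 tags led by CATGCTGCTTTAATATATGTT took 0.0228% of copies at stage 1, 8.87% at stage 2, 7.91% at stage 3, 11.9% at stage 4 and 9.89% at stage 5. Its sum was 390-fold higher in stage 2 than in stage 1 (counting interval 369.8 to 412). A set of 9 tags led by CATGCATGCAACCTAAATACT was 468-fold higher in stage 2 than in stage 1 (417 to 528) and took 3.78% of stage 5. The folds of sets are on library totals, and the TMM shift of 1.21 on the log2 scale for stage 2 against stage 1 would raise these 2. A set of 6 led by CATGCAATTTCCTTCTCTTCA took 0.323%, 0.562%, 0.817% and 1.42% at stages 2 to 5. Of the sets that were also higher in stage 2 than in stage 1, some were lower at the last step. Among them were a set of 8 led by CATGTGGTTTTGATGGGTAAA, 17.2-fold lower in stage 5 than in stage 4 (16.8 to 17.6), and a set of 3 led by CATGGGGATCGGAACTAGGGA, 23.1-fold lower (22.4 to 23.7).

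Some tags matched the first bases of an abundant tag and then continued in A alone, as a transcript would that ends within the tag. Only those with at least 12 bases before a run of at least 5 A were counted. Where abundant tags shared these A-ended tags, their copies were pooled so that each copy counted once. For CATGCTGCTTTAATATATGTT, pooled with 1 other tag that has the same first bases, A-ended tags made up 1.85% of the summed copies at stage 2 (counting interval 1.80 to 1.91), 3.896% at stage 3, 3.13% at stage 4 and 4.31% at stage 5 (4.24 to 4.38). The course depended on the tag the same A-ended copies were set against: they made up 2.03% at stage 2 and 6.02% at stage 5 against the named tag alone, and 17.6% and 13.2% against CATGCTGCTTTAATATGTGCT alone. For CATGCTGTTTTAATATATGTT the share was 2.55% at stage 2, 5.66% at stage 3, 4.15% at stage 4 and 3.14% at stage 5. Over the 46 of 118 groups with at least 500 copies of the abundant tags in each of stages 2 to 5 and 100 A-ended copies over these stages, 11 of them pooled, the share was higher in stage 5 than in stage 2 for 40 and lower for 6. In the 26 groups with enough copies at stage 1, the share was lower in stage 2 than in stage 1 for 15 and higher for 11, and in stage 5 it was higher than in stage 1 for 21 and lower for 5. Tags ending in 8 A made up 2.74%, 2.00%, 3.25%, 3.69% and 3.69% of all copies at stages 1 to 5.

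The stage 1 library stood apart, with r at or below 0.37 to every other library among tags reaching 10 TPM and 6234 tags lower against 1645 higher in stage 2. A stage 1 library of another organism than the other libraries is argued against. Of 14547 stage 1 tags at 10 TPM or more, 98.7% were listed in another library and 86.4% in all 4 others. An organism shared by all libraries, as the mention of pear fruit in the labels could mean, cannot be judged this way, since no reference sequence was used. The excess of lower tags may come from a few very abundant tags taking most of the counts: with libraries scaled to copies outside the 235 tags among any library's top 100, 58.7% of called tags were lower (3082 lower, 2171 higher) in place of 79.1%. Any scaling that raises stage 2 lowers this share whatever the cause, so the fall does not single out the abundant tags, and lower tags still outnumbered higher ones. On a fixed set of tags, 1 factor per library shifts all tags alike on the log scale, apart from the pseudocount, and so would not lower r. The choice of tags at 10 TPM does depend on the scaling, with 14547 such tags in stage 1 and 7616 in stage 2. Because r was not recomputed on tags chosen after another scaling, the part of scaling in the low r among tags reaching 10 TPM was not tested. Over all 242991 tags r was 0.75 with stage 2 and 0.60 with stage 5, and the difference between stages, the library preparation and the plants sampled stay open with 1 library per stage.

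Tags that overlap with CATG sites 4 to 6 bases apart may come from 1 transcript, and the change of their ratio between libraries was then taken as a measure of noise. This was not checked against transcript sequences, and copies lacking the upstream site could change the ratio too. In 13 such pairs with at least 20 copies of both tags in every library, the ratio varied with a median SD of 0.34 on the log2 scale, and of 0.28 beyond counting error. Counting error alone is argued against, with a median chi-square per degree of freedom of 12.3. Cutting that differed between libraries as a whole stays open: at stage 5 84.6% of pairs (11 of 13) leaned the same way, with an exact two-sided binomial p of 0.0225 and an adjusted p of 0.112 over the 5 libraries. The median change of ratio between 2 libraries was 1.29-fold, and 1 pair of the 13 changed by 4-fold or more, the size used to call tags.

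Tags 1 base apart changed their ratio more than that. The comparison took 128 pairs in which both tags reached 100 TPM and had at least 20 copies in every library. Tags ending in more than 5 A were left out. Of these pairs, 39.8% varied beyond the 95th percentile of the overlapping pairs (bootstrap interval 27.3 to 67.97%). That percentile, 0.74 on the log2 scale beyond counting error, rested on 13 pairs and lay between their largest value, 0.89, and the next, 0.64. The interval does not give the spread of the 128 pairs, some of which share a tag. The share argues against noise of the size seen in the 13 pairs as the whole cause, but not against larger noise. Pairs with a tag under 20 copies in any library, whose ratios can change more, were not among the 128. The minor tag exceeded 5% of the major one in its highest library in 98.4% of pairs, but this decides nothing on sequencing errors, since in 99 pairs the major tag stayed under 2000 TPM and the minimum of 100 TPM fixed the outcome. In 93.1% of the 29 other pairs the minor tag exceeded 5% in the library where the major tag was highest (exact interval 77.2 to 99.2%). The median share there was 28.3%. The minimum of 100 TPM favoured high shares here too, most where the major tag was little above 2000 TPM. The interval takes pairs as independent, though some share a tag. Shares of that size argue against sequencing errors for these selected pairs only, and give no estimate for rarer neighbours. Sequence variants of transcripts in the plants sampled stay open as a candidate explanation: with error neighbours merged, 37.1% of the 591 tags called for stage 3 against 2 had a tag 1 base away at 10 TPM or more, against 15.1 to 26.9% in 1000 random draws at the share of uncalled tags of like abundance, and for stage 4 against 3 it was 49.6% of 250, against 18.8 to 34.8%, yet the neighbour moved in the opposite direction, as an exchange of variants would need, for 26.0% (57 of 219) and 33.1% (41 of 124) of the tags that had one. In the 3 other comparisons the excess was smaller, 24.5% for stage 2 against 1, 26.03% for 5 against 4 and 24.5% for 5 against 1, against up to 22.2%, 24.3% and 22.1%, and the neighbour moved in the opposite direction for 4.12%, 8.53% and 4.94%. Near-identical gene copies used at different stages would give the same excess.

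An example picked after its values were seen is a variant in the set of 27 tags. CATGCTGCCTTAATGTATGTT, A15G relative to CATGCTGCCTTAATATATGTT, was unlisted at stage 1 and stood at 2.21, 4.79, 837 and 2.20 TPM at stages 2 to 5, while the common tag stood at 10456 at stage 3, 10130 at stage 4 and 10421 at stage 5. The overlapping tag CATGCATGCTGCCTTAATGTA carries a base change A19G and had 0.340, 0.855 and 181 TPM at stages 2 to 4 and none listed at stage 5.

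The count of tags with a trend was set against every order of the 5 libraries. Of the 60 orders, with mirrored ones taken as 1, 2 called as many tags as the real one, itself included. The real order called 136 tags, the order with stages 3 and 4 exchanged called 289, and the remaining 58 called 0, so this count hardly ranks the orders. At an unadjusted p under 0.05, where every order gave a count, the real order had 4838 tags, the highest of the others 4812, again with stages 3 and 4 exchanged, and their median was 462. By the unadjusted count the real order ranked first, but the order of stages 3 and 4 was not separated. That count was chosen after the results were seen, and 60 orders of unreplicated libraries cannot exclude chance. The real order called 0 tags without any 1 library, with a minimum of 50 TPM, or with unlisted tags at 1 copy.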
